A study of Mus musculus with 2 samples.

How the data were processed

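Whole mesentery of 2 untreated adult male C57BL/6N mice, a wild-type inbred strain, was digested with Liberase DH, a collagenase blend, and single cells were captured on the Chromium system with version 2 of its 3′ chemistry, per the labels' protocols. Both animals form 1 group, so nothing was compared between them. The deposited values are raw UMI counts per gene and cell barcode, whole numbers with no normalization, per the file headers. Cell Ranger and the mouse build mm10 are named in the submitters' processing notes; a version is not given in the sources used here, nor whether the depth of the libraries was equalised. The matrix held 27998 genes and 3204 barcodes. A suffix of 1 or 2 on each barcode marked the library and was matched by number to the mouse; exchanging the numbers would change only which library is called 1. The threshold that chose the deposited barcodes is not given in the sources used here.

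Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 61. Scrublet in scanpy 1.11.5 was run on each library and called 39 doublets in library 1 and 4 in library 2, at automatic score thresholds of 0.163 and 0.313, so the share removed differed between the libraries. After their removal 3100 cells were analysed. Counts were scaled to 10000 per cell and log-transformed; 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with seed 0 gave 16 clusters. Pdgfra, Pdpn and the lists of ILC2 niche factors, ILC2 receptors and ILC2 effectors were kept out of the clustering. Each cluster took the class whose markers had the highest mean log2 fold over the other cells, with an offset of 0.1 per 10000 and at least 3 markers above 2-fold in at least 10% of its cells. Of the 289 list genes and 194 marker genes, 5 and 7 did not match exactly 1 row of the matrix. Any gene not kept out of the clustering could be among the 2000 variable genes that defined the clusters, and the markers named them. Tests of such genes therefore describe the classes and are not independent of them.

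Raw counts were summed per library and class, giving 22 sums for 11 classes with at least 10 cells in each library. The quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) was run with TMM factors, filterByExpr and library as a block, with Benjamini-Hochberg adjustment and calls at an adjusted p of 0.05. The same animal gave every class, which is why library is a block. The fit borrows its residual spread from the classes: with 2 animals, p-values rest on how far the libraries differ within classes. Fibroblast-like cells were compared with the equally weighted mean of the other 10 classes, which is a mean of logarithms, and with mesothelial-like cells; each of the 4 fibroblast-like clusters was compared with the mean of the other clusters of the class. The mean of the other clusters is a mean of logarithms as well. In the comparisons with a mean of classes or clusters, a class or cluster with 0 UMIs of a gene leaves that mean almost free to fall. Genes low in fibroblast-like cells and at 0 in some other class could therefore not be called. Fitted folds of genes at 0 in some class or cluster are not bounds. Levels are therefore given as CPM, UMIs scaled to a total of 1000000, computed from the deposited counts, as mean ± SD of the 2 libraries, beside the arithmetic mean of the other classes. The 17 gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one. Intervals of shares are exact Clopper-Pearson intervals at 95%, and those of CPM are exact Poisson intervals; both cover counting error only. The limit for a count of 0 is 3 counts. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names.

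Named genes were, per comparison, the 10 with the largest positive and the 10 with the largest negative log2 fold change among those called, with an average log2 CPM of at least 5 and the same direction in both libraries. To these were added each detected niche factor in the comparison with the other classes, Pdgfra and Pdpn throughout, up to 4 members of each other list, and the 5 largest positive genes of each cluster. Il33 was added to the comparisons with mesothelial-like cells and between clusters after the data were seen. Lists, markers, tests and most alternatives were fixed before the data were examined. Alternatives were DESeq2 size factors, DESeq2's Wald test (version 1.42.0), no filter on low counts, no replicate block, each library left out, other clustering resolutions of 0.5 and 2.0, at least 500 genes with at most 5% mitochondrial UMIs, no doublet removal, other classes summed over cells, and thinning to 500 or 2000 UMIs or none. A fit without the pericyte-like class was added after the data were seen.

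The fits were tested on simulated data with 200 genes changed at a dispersion of 0.1. Against the other classes, over 7784 genes, 17% of genes changed by 1 on the log2 scale and 65% of those changed by 2 were called in the right direction; 12 unchanged genes were called, 12.8% of the calls, and unchanged genes were shifted by a median of 0.19. Against mesothelial-like cells the shares were 3% and 49%, with 0 unchanged genes called. For 1 fibroblast-like cluster over 5494 genes they were 14% and 67%, with 3.6% of calls on unchanged genes. In the data 3851 genes were called against the other classes and 2624 against mesothelial-like cells, far more than the 200 changed here. The dispersion was set by hand and not fitted to the data. These rates therefore do not carry over to the real calls, whose share of unchanged genes is not known. Calls against the other classes are to be read as including some unchanged genes.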

Results

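Single-cell transcriptomes of whole mouse mesentery were collected to describe mesenchymal cells that carry PDGFRα and gp38, the product of Pdpn, and that the study links to group 2 innate lymphoid cells (ILC2). The 2 libraries, 1 per mouse, held 1517 and 1687 barcodes with 5137671 and 5563521 UMIs in total. The median barcode had 3065 UMIs in library 1 and 2663 in library 2. After filtering, 1445 and 1655 cells were analysed.

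Fibroblast-like cells were the most frequent of the 11 named classes, at 31.8% of cells in both libraries, with exact 95% intervals of 29.4 to 34.3% and 29.6 to 34.2%. Endothelial-like cells made up 11.2% ± 1.80 (SD, n = 2), T-like cells 11.1% ± 0.286, and macrophage-like cells 8.34% ± 0.343. B-like cells were 9.27% of library 1 (7.83 to 10.9%) and 6.16% of library 2 (5.05 to 7.43%). Mesothelial-like cells, the lining of the peritoneal surface, made up 4.64% of library 1 (3.61 to 5.85%) and 10.7% of library 2 (9.25 to 12.3%). ILC2-like cells were 4.14% ± 0.990, with 70 and 57 cells. Pericyte-like, monocyte-like and NK- or ILC1-like cells made up 5.07%, 4.89% and 2.96%, and dendritic-like cells 3.39% of library 1 and 5.02% of library 2. A cluster of 29 cells was left unnamed. The pericyte-like cluster also carried endothelial transcripts. The endothelial-like cluster was led by Car3 and held 3 adipocyte markers above 2-fold. At a clustering resolution of 2.0, a cluster of 66 cells was named adipocyte-like and held 11 blood endothelial markers above 2-fold.

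**Figure D1:**
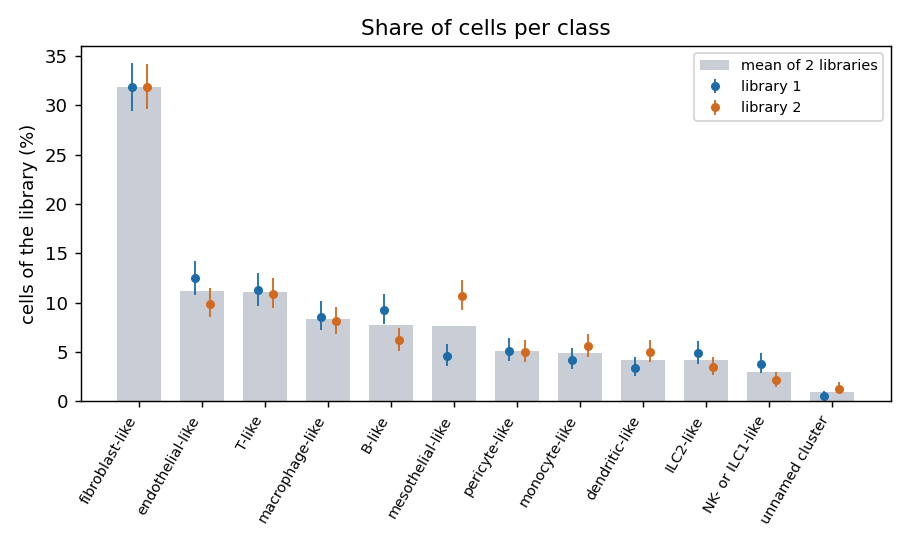
Share of cells per class in percent of all analysed cells of a library; grey bars are means of the 2 libraries, points are libraries and lines are exact 95% intervals, which cover counting error only. Fibroblast-like cells stand at 31.8% in both libraries, and mesothelial-like cells at 4.64% and 10.7%.

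The surface phenotype of interest was followed at the RNA level through Pdgfra, a receptor for platelet-derived growth factor (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), and Pdpn (ENSMUSG00000028583, chromosome 4, 143267431 to 143299564). Pdgfra was highest in fibroblast-like cells, at 239.5 ± 22.4 CPM (SD, n = 2) against a mean of 8.92 and 14.6 CPM over the other classes. Pdpn stood at 217.8 ± 48.7 CPM in fibroblast-like cells and was highest in mesothelial-like cells, at 482.2 ± 45.7 CPM. After thinning to 1000 UMIs, 13 of 455 fibroblast-like cells in library 1 had UMIs of both genes (2.86%, exact interval 1.53 to 4.84%) and 31 of 507 in library 2 (6.11%, 4.19 to 8.57%), with 5 and 20 shallower cells left out. Independent detection of the genes would give 3.05% and 5.98%, inside these intervals. Without thinning the shares were 26.5% and 22.6%, so the share with both moved with depth. In T-like cells, which should lack both, 0 of 323 thinned cells had both, which allows up to 0.929%, and 1 of 343 had both before thinning (0.292%); the median cell had 1618 UMIs there and 3385 in the fibroblast-like class. Of 131 thinned dendritic-like cells 1 had both (0.763%, 0.0193 to 4.18%), with 0.245% under independence. Before thinning 20 of 132 had both (15.2%, with 4.50% under independence), and the median cell of this class had 5066 UMIs. Of endothelial-like cells before thinning, 0 of 180 had both in library 1 and 7 of 164 in library 2 (4.27%, with 0.372% under independence).

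**Figure D2:**
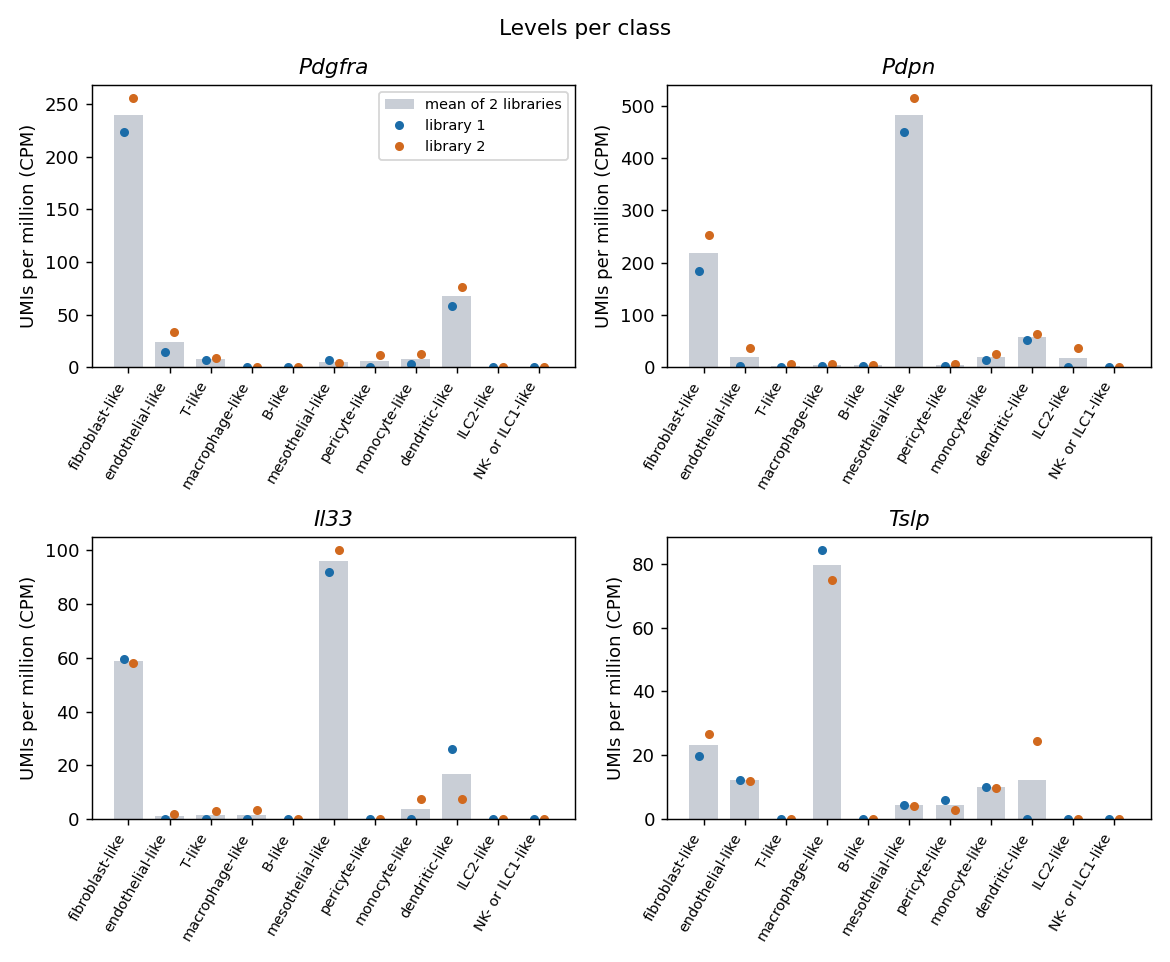
Levels of Pdgfra, Pdpn, Il33 and Tslp in CPM of the summed class; grey bars are means of the 2 libraries and points are libraries. Pdgfra is highest in fibroblast-like cells at 239.5 CPM, Pdpn and Il33 in mesothelial-like cells at 482.2 and 95.95 CPM, and Tslp in macrophage-like cells at 79.55 CPM.

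The largest increases in fibroblast-like cells over the mean of the other classes were Krtdap, Col14a1, Ptx3, Has2, Pi16, Aspn, Vcan, Inmt, Col1a1 and Nov. Of these, Col1a1 is one of the markers that named the class. Col14a1, a fibril-associated collagen, stood at 845.1 ± 125 CPM against 15.3 and 37.2 CPM over the other classes (log2 fold change 6.94, SE 0.26, adjusted p = 3.25e-24, edgeR). Pi16, a peptidase inhibitor of fibroblasts, reached 722.9 ± 108.7 CPM against 7.01 and 22.6. The largest decreases were Tm6sf1, Rab11fip1, Hcls1, Ccr2, Gimap5, Il2rg, Ucp2, Bcl2a1b, Srgn and Epsti1. Srgn, the proteoglycan core of leukocyte granules, was at 14.1 ± 1.96 CPM against 887.9 and 762.3. DESeq2's Wald test did not call Krtdap (adjusted p = 0.269), and edgeR no longer called Rab11fip1 and Ccr2 without doublet removal, or Bcl2a1b and Epsti1 at a clustering resolution of 2.0. Of 7784 genes tested, 3851 were called by edgeR, 2508 higher and 1343 lower. Summing the other classes over cells turned that balance, with 2415 higher and 2771 lower among 10852 genes tested. DESeq2 size factors moved the median log2 fold change of all genes from 0.08 to 0.18.

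Among 34 ILC2 niche factors, secreted or surface proteins reported to act on ILC2 or their progenitors, 22 were tested, 13 were higher in fibroblast-like cells, 1 was lower and 8 were not called; adjusted over the list alone the counts were also 13 and 1. As a set the list was not called by camera (adjusted p = 0.0805, and adjusted p = 0.165 with an estimated correlation). Il33, an alarmin read through the receptor Il1rl1 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718), stood at 58.75 ± 0.902 CPM against 11.8 and 12.3 CPM over the other classes (adjusted p = 4.24e-14, edgeR). Il6 was at 460.3 ± 14.4 CPM against 83.5 and 95.96, and Csf1, a macrophage growth factor, at 271.1 ± 33.6 CPM against 24.5 and 32.2. Tslp, Vcam1, Tgfb2, Tgfb3 and Jag1 were also called higher, Tgfb3 not with the other classes summed over cells (adjusted p = 0.187, edgeR). Il18, Cxcl12, Cxcl16, Tgfbi and Bmp4 were called against the mean of logarithms, but Cxcl12, Cxcl16, Tgfbi and Bmp4 had a higher arithmetic mean over the other classes than in fibroblast-like cells, and all 5 changed sign when the other classes were summed. Tgfbi was not called at a clustering resolution of 0.5 (adjusted p = 0.158, edgeR) or without the pericyte-like class (adjusted p = 0.0886). Cxcl12 was highest in endothelial-like cells at 575.5 ± 85.3 CPM, against 109.9 ± 3.73 in fibroblast-like cells. Tgfb1 was lower, at 58.8 and 60.6 CPM against 376.8 and 344. Kitl, Flt3l, Icam1, Csf2, Tnfsf11, Dll4, Calca and Areg were not called; Csf2 stood at 10.4 and 1.24 CPM in fibroblast-like cells, was called higher under 5 alternatives and lower with the other classes summed over cells, and Calca and Areg were at or under 1.15 CPM. DESeq2 called Dll4 and Areg lower (adjusted p = 0.0312 and 0.00416), and Kitl, Tnfsf11, Dll4, Calca and Areg were called lower with the other classes summed over cells.

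Of the other fixed lists, all 25 tested genes of collagens and matrix were higher, as were 17 of 18 matrix proteases and inhibitors, 15 of 15 universal fibroblast progenitor genes, 15 of 17 Wnt and BMP ligands and antagonists, 10 of 12 growth factors, 9 of 9 retinoic acid genes and 8 of 11 chemokines. Each of these 7 lists was called upward by camera with the preset and the estimated correlation, the largest estimated adjusted p being 0.0212. Collagens and matrix share Col1a1, Col1a2, Col3a1, Dcn and Lum with the markers that named the class, so these were bound to be higher. Adjusted over the list alone, the counts were the same except for 16 Wnt and BMP genes. With the other classes summed over cells, the retinoic acid genes Aldh1a1 and Rarres2 changed sign, as did the chemokines Cxcl12 and Cxcl16. Aldh1a2 was then not called (adjusted p = 0.0983, edgeR). Bmp4 of the Wnt and BMP list, Enpp2 of lymphoid stroma and Hspb1 of dissociation stress were then called lower (adjusted p = 0.0021, 0.032 and 1.3e-07, edgeR). All counts given here are calls against the mean of logarithms. The growth factor Fgf1 and the complement genes C2 and Cfb were called higher. Their arithmetic mean over the other classes was nevertheless above their fibroblast-like level. DESeq2 did not call Aldh1a3 or the Wnt antagonist Sfrp4 (adjusted p = 0.0791 and 0.314). Among the chemokines, Ccl7, Ccl2 and Ccl11, attractants of monocytes and eosinophils, stood at 3774 ± 187.3, 2477 ± 4.08 and 1350 ± 77.3 CPM. In antigen presentation 9 of 12 genes were lower (adjusted p = 0.0295 with an estimated correlation), with Cd74 at 65.7 and 14.2 CPM against 8849 and 4990. In ILC2 receptors 6 of 18 were lower and 3 higher (adjusted p = 0.0209 with an estimated correlation). Of the lower ones, edgeR did not call Itga4 at resolution 2.0 or with the stricter filter, nor Tnfrsf18 at resolution 2.0. Lymphoid stroma, with 5 of 7 higher, and dissociation stress, with 15 of 19 higher and 1 lower, were called with the preset correlation but not with the estimated one (adjusted p = 0.0644 and adjusted p = 0.199 with an estimated correlation). Complement (8 higher and 1 lower of 14), preadipocyte genes (5 and 3 of 12), ILC2 effectors (3 and 3 of 15), mesothelial function (2 and 2 of 10) and cell cycle (0 and 1 of 6) were not called as sets by camera. With DESeq2 size factors camera called ILC2 effectors and cell cycle downward (adjusted p = 0.0366 and 0.0456), and without the replicate block ILC2 effectors (adjusted p = 0.0372). In all these, the counts adjusted over the list alone were the same.

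Mesothelial-like cells share Pdpn with fibroblast-like cells and were compared with them directly. Pdgfra was higher in fibroblast-like cells, with 5.34 ± 1.94 CPM in mesothelial-like cells (log2 fold change 5.74, SE 0.32, adjusted p = 9.74e-18, edgeR). Pdpn was lower in fibroblast-like cells (log2 fold change −1.02, SE 0.21, adjusted p = 1.42e-04, edgeR), a call that DESeq2's Wald test did not make (adjusted p = 0.179). Il33 was at 95.95 ± 5.90 CPM in mesothelial-like cells, and its difference from fibroblast-like cells missed the threshold (log2 fold change −0.59, SE 0.24, adjusted p = 0.0509, edgeR) but passed it under 4 alternatives, among them DESeq2 size factors (adjusted p = 0.0430 by edgeR). Of 7784 genes, 1224 were higher and 1400 lower in fibroblast-like cells, a balance that turned to 1299 and 1263 at a clustering resolution of 2.0. DESeq2's Wald test did not call Ebf2, Krt19, Krt7 and Igfbp2 among the genes named next.

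The genes highest in fibroblast-like over mesothelial-like cells were Aspn, Pla1a, Ebf2, Efhd1, Cilp, Dpt, Has2, Nov, Fam150b and Svep1. Aspn, Pla1a, Ebf2, Efhd1, Cilp, Has2, Nov and Fam150b had 0 UMIs in mesothelial-like cells, which allows up to 6.72 CPM in library 1 and 2.97 in library 2. Dpt, a matrix protein and one of the markers that named the fibroblast-like class, was at 1767 ± 18.4 against 4.09 ± 2.62 CPM. The genes highest in mesothelial-like cells were Lrrn4, Krt19, Krt7, Upk3b, Krt18, Igfbp2, Slpi, Gpm6a, Msln and Ano1, several of which are the markers that named the class. Outside the markers, Fgf1 was at 937.4 ± 51.3 CPM in mesothelial-like and 19.2 ± 2.63 in fibroblast-like cells, and Rarres2, the precursor of chemerin, at 3179 ± 280.6 and 619.6 ± 132.3. The complement genes C2 and Cfb were at 386.3 ± 23.4 and 237 ± 2.74 CPM in mesothelial-like cells, against 10.8 ± 3.06 and 10.5 ± 1.78. Among niche factors, Tslp, Il6, Csf1, Csf2, Cxcl12, Vcam1, Tgfb1 and Jag1 were higher in fibroblast-like cells, and Kitl, Il18, Cxcl16, Tgfb3, Tgfbi and Bmp4 in mesothelial-like cells. Bmp4 stood at 146.1 ± 11.8 CPM in mesothelial-like and 22.9 ± 2.67 in fibroblast-like cells. The Csf2 call rests on 1 library, with a log2 fold change of 2.57 without library 1 in place of 4.55, and was not made by DESeq2 (adjusted p = 0.495).

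Among the fixed lists, chemokines were higher in fibroblast-like than mesothelial-like cells in 8 of 11 genes and lower in 1, and mesothelial function was lower in 9 of 10. Both were called by camera with either correlation (adjusted p = 0.00703 and adjusted p = 0.00345 with an estimated correlation). Among the chemokines, Ccl8 was not called with the stricter filter (adjusted p = 0.0748, edgeR) or by DESeq2's Wald test (adjusted p = 0.741). That test also did not call Muc16 of mesothelial function (adjusted p = 0.406). Adjusted over the list alone the counts were 8 and 1 for chemokines and 10 lower for mesothelial function, a list that shares Muc16, Msln and Upk3b with the markers that named the class. Of 11 tested markers of blood endothelium, 10 were also higher in mesothelial-like cells, among them Pecam1, Cdh5, Kdr and Flt1, and 1 was lower. The median log2 fold change was −2.28 against −0.05 for all genes. Endothelial-like cells stood 13.3-fold (Pecam1), 51.9-fold (Cdh5) and 46.2-fold (Flt1) above the highest other class, the pericyte-like one aside. The mesothelial-like levels of these genes were thus a small part of the endothelial-like ones, and the cause was not tested. Of 3 tested adipocyte markers, Cidec and Retn were higher in mesothelial-like cells. The counts for both marker lists were the same adjusted over the list alone. Aqp1, counted under mesothelial function, is also among the genes with the highest fold in endothelial-like cells. Collagens and matrix (23 of 25 higher), matrix proteases (11 higher and 2 lower of 18), universal fibroblast progenitor genes (10 and 1 of 15) and antigen presentation (7 of 12 lower) were called with the preset correlation alone. With an estimated correlation they had adjusted p = 0.0520, 0.189, 0.189 and 0.223 by camera. Adjusted over the list alone these counts were 24, 11 and 2, 12 and 1, and 7. Of the ILC2 niche factors 8 were higher and 6 lower (8 and 7 adjusted over the list alone), with no call as a set (adjusted p = 0.694, camera). Dissociation stress genes were higher in 5 of 19 and lower in 7 (5 and 8 adjusted over the list alone).

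The fibroblast-like class held 4 clusters. Any gene other than those kept out of the clustering could help to define them. Counts of calls, the leading genes and the progenitor, preadipocyte, matrix and stress lists therefore describe each cluster and are not independent of it. The largest increases in cluster 6 were Dmkn, Igfbp5, Krtdap, Gm15675 and Myoc, the last of which also led cluster 14. Igfbp5, a binding protein of insulin-like growth factors, was at 1480 ± 203.3 CPM in cluster 6 against 34.8 and 13.5 over the other clusters. Of 15 universal fibroblast progenitor genes, 14 were higher and 1 lower there, with the same counts adjusted over the list alone. Il33, kept out of the clustering, was higher in cluster 6, at 97.6 ± 0.114 CPM against 33.7 and 35.3 (log2 fold change 1.49, SE 0.22, adjusted p = 2.29e-06, edgeR). Tgfb2 and Jag1 were higher with it, while Il6, Csf1, Cxcl12, Cxcl16, Icam1, Vcam1, Tgfbi and Bmp4 were lower, and these counts were the same adjusted over the list alone. Pdgfra was lower in cluster 6, at 172.1 ± 25.6 CPM, and Pdpn was not called (adjusted p = 0.222, edgeR). Of 19 dissociation stress genes, 14 were lower and 1 higher in this cluster (15 and 2 adjusted over the list alone). DESeq2 did not call Myoc or Bmp4 in it (adjusted p = 0.174 and 0.131). Of 5494 genes, 633 were higher and 651 lower, a balance that turned to 875 and 560 without the filter on low counts, and 525 were called by DESeq2.

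Cluster 4 was led by Cxcl14, Nmb, G0s2, Iigp1 and Fam150b, with Cxcl14 at 301.8 ± 119.1 CPM. Cxcl12, the ligand of Cxcr4, was at 277.6 ± 15.6 CPM against 71.6 and 54.1 over the other clusters (log2 fold change 2.54, SE 0.18, adjusted p = 1.02e-12, edgeR), and Il6 reached 806.3 ± 139.1 CPM. Icam1, Cxcl16, Bmp4 and Vcam1 were called higher, although Vcam1 stood at 83.2 CPM in library 1 and 27.5 in library 2, below the other clusters at 39.2 in the latter. Il33 was lower, at 27.7 and 22.9 CPM against 57.0 and 60.2 (adjusted p = 0.0290, edgeR), a call lost without the filter on low counts (adjusted p = 0.0542). The mean of the other clusters includes cluster 6, so the Il33 call in part restates the increase there. With both libraries pooled and thinned to 1000 UMIs, 2.903% of cluster 4 cells had an Il33 UMI. The shares were 3.211% in cluster 5, 3.077% in cluster 14 and 8.553% in cluster 6. Cluster 4 was not tested against clusters 5 and 14 alone. Tgfb2 was the other niche factor called lower. DESeq2 called neither Il33, Vcam1, Cxcl16 nor Bmp4 here, and edgeR did not call Vcam1 without the replicate block (adjusted p = 0.0630); without library 1 its log2 fold change was −0.16. Preadipocyte genes were higher in 7 of 9 and lower in 1, also adjusted over the list alone, and 12 of 15 progenitor genes were lower (14 adjusted over the list alone). Of 19 dissociation stress genes, 9 were higher and 3 lower (10 and 3 adjusted over the list alone). Of 5494 genes 455 were higher and 331 lower, and 285 in all by DESeq2.

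Cluster 14 was led by Myoc, Mfap4, Mmp3, Tgfbi and Mgp. Mgp, an inhibitor of calcification, was at 4105 ± 526.6 CPM, and Mfap4, a microfibril protein, at 448.6 ± 105.9. Myoc stood at 224.3 CPM in library 1 and 18.7 in library 2, so its place rests on 1 library; without that library the log2 fold change was 3.59 in place of 6.07. Tgfbi and Bmp4 were the niche factors called, both higher. Of 26 collagen and matrix genes, 12 were higher and 1 lower (12 and 4 adjusted over the list alone). Of 19 dissociation stress genes 6 were higher (8, with 1 lower, adjusted over the list alone). DESeq2 did not call Myoc (adjusted p = 0.185). In all 252 genes were higher and 128 lower, a balance that turned to 208 and 246 without the filter on low counts, and 157 were called by DESeq2.

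Cluster 5 was the least distinct, with 110 genes higher and 45 lower, and 57 called without the replicate block. Has2, Mcoln2, Cx3cr1, Nov and Smpd3 led it, with Smpd3, a sphingomyelinase, at 331 ± 85.5 CPM. Mcoln2 stood at 23.3 CPM in library 1, below the other clusters at 27.4, and at 73.1 in library 2. Il6, Csf1 and Icam1 were higher by 0.67, 0.67 and 0.70 on the log2 scale with the library block; none of the 3 was called without the block, with adjusted p = 0.116, 0.0601 and 0.0697 (edgeR), or by DESeq2. Of 19 dissociation stress genes 0 were higher and 6 lower (4 and 7 adjusted over the list alone). Neither Pdgfra nor Pdpn was called in clusters 4, 5 and 14.

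**Figure D3:**
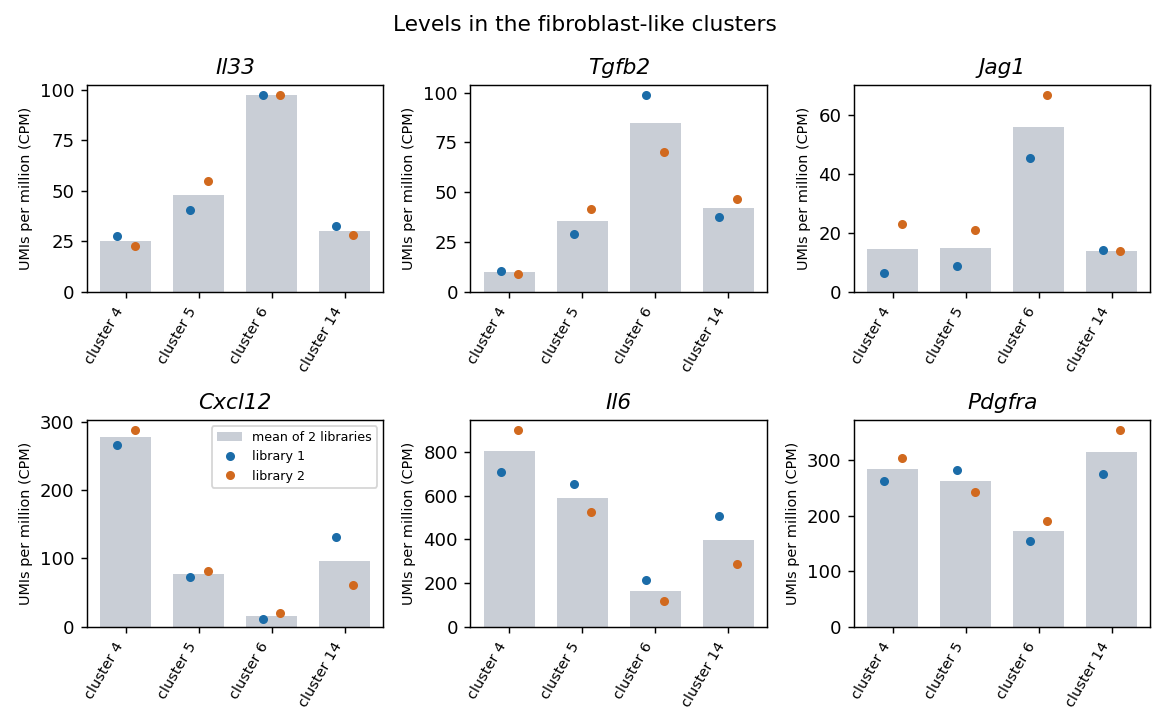
Levels of 6 genes kept out of the clustering in the 4 fibroblast-like clusters, in CPM of the summed cluster; grey bars are means of the 2 libraries and points are libraries. Il33, Tgfb2 and Jag1 are highest in cluster 6 and Cxcl12 and Il6 in cluster 4, where they reach 277.6 and 806.3 CPM.

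Receptors and effectors of ILC2 were followed in ILC2-like and T-like cells, without a test of the lists as sets. Il1rl1, the Il33 receptor, was at 801.2 ± 74.7 CPM in them and at 110.5 ± 14.8 in T-like cells, and is one of the markers that named the class. Il7r, which pairs with Crlf2 to read Tslp, was at 334.2 ± 37.4 CPM in ILC2-like and 429.9 ± 1.11 in T-like cells, and Crlf2 was at 94.4 ± 18.8 and 97.9 ± 25.8. Csf2, outside both the markers and the clustering, was at 1613 ± 192.4 CPM in ILC2-like and 27.1 ± 20.1 in T-like cells. Arg1 stood at 454.1 ± 119.4 and 7.79 ± 2.67 CPM. In fibroblast-like cells Il1rl1 was at 0 CPM in library 1, which allows up to 1.73, and at 3.09 in library 2.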

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

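The pair of Dcn and Ptprc was chosen after the data were seen, and no explanation was tested for the values that follow. The unnamed cluster and the barcodes of few genes entered no comparison, and each held a signal above the limit that a count of 0 allows. In the unnamed cluster 15 of 29 cells (51.7%, exact 95% interval 32.5 to 70.6%) had UMIs of both Dcn, a matrix proteoglycan, and Ptprc, the leukocyte antigen CD45. Ptprc was seen in 10 of 987 fibroblast-like cells (1.01%). The median cell had 4840 UMIs in the unnamed cluster and 3385 in the fibroblast-like class. Hemoglobin transcripts made up 72.0% of the UMIs in the 16 barcodes under 200 genes of library 1, and 98.4% in the 8 of library 2.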

How the results depend on the processing

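The fit without the pericyte-like class was chosen after the data were seen. Of 2448 values of named genes under an alternative, 2209 kept their direction and side of the threshold or, with a library left out, moved by less than the libraries differ. The latter were 192 values without library 1 and 163 without library 2. Their margin was the SD of the 2 left-out values, which grows with the gap between the libraries. These values therefore do not show that the libraries agreed: Csf2 against the other classes, at −0.21 and 2.68, was counted among them both times. Of the others, 50 lost their call, 30 gained one, 138 moved without a test and 21 were counted as changing sign. DESeq2's Wald test accounts for 28 of the lost calls. With a library left out, a change of sign was counted only for genes called in the main fit. Against the other classes, Csf2 (−0.21 without library 1) and Icam1 (−0.067 without library 2) also changed sign but are outside the 21. Leaving out 1 library leaves no residual spread, so those are values with no test and give no count of calls. Without the replicate block, 3593 genes were called against the other classes, 2277 against mesothelial-like cells, and 982, 559, 276 and 57 in clusters 6, 4, 14 and 5; beside the genes named for cluster 5, Vcam1 in cluster 4 was the only named gene to lose its call. DESeq2's Wald test called 525, 285, 157 and 48 genes in clusters 6, 4, 14 and 5; the cause was not tested. Il33 against the other classes was 4.96 and 6.20 on the log2 scale with either library left out. B-like, ILC2-like, NK- or ILC1-like and pericyte-like cells had 0 Il33 UMIs, so these fitted folds are not bounds. They exceed the difference in CPM given above, and the mean CPM was higher in mesothelial-like than in fibroblast-like cells. The fibroblast-like share was 32.9% and 31.8% (31.81) at resolutions 0.5 and 2.0, 35.3% with the stricter filter and 31.5% without doublet removal. Without doublet removal the ILC2-like share was 5.37%, as a cluster of 34 cells took that name. Its leading genes included Wdyhv1, Il13 and Wdr20, as did those of the unnamed cluster, and the fibroblast class ranked second for it. At resolution 2.0 a cluster of 26 cells led by Tnfrsf4, Ikzf2, Il10, Ctla4, Foxp3, Il1rl1, Il2ra and Klrg1 also took the ILC2-like name. The T class ranked second for it, with 6 markers above 2-fold beside 7 ILC2 markers, so its name is uncertain. At that resolution 66 cells were named adipocyte-like. At 0.5 no cluster was named NK- or ILC1-like, and a T-like cluster of 340 cells was led by Gzma, Ccl5 and Nkg7. Fibroblast-like cells with both Pdgfra and Pdpn were 0.909% at 500 UMIs, 9.92% at 2000 and 24.6% unthinned, as depth sets detection. With the other classes summed over cells, which weights each class by its UMIs, the log2 fold changes were −2.90 for Kitl, −0.59 for Il18, −3.28 for Csf2, −0.33 for Cxcl12, −0.86 for Cxcl16, −0.17 for Icam1, −1.83 for Tgfbi, −0.89 for Bmp4, −0.50 for Enpp2, −0.0026 for Rarres2, −0.48 for Aldh1a1, −2.002 for Cpe and −1.46 for Hspb1. Kitl was −0.064 by DESeq2. Tnfsf11 was 0.78 and 0.20, Calca 0.95 and 0.76, and Bcl11b against mesothelial-like cells 0.048 and 0.31, at resolution 0.5 and with the stricter filter; none was called in any of these. Vcam1 in cluster 4 was −0.16 without replicate 1 and 1.77 without replicate 2; the cause was not tested.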

Other observations

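The tests of free RNA and fibroblast doublets for Tslp, of dissociation stress, and of admixed RNA in cluster 5 were chosen after the results were seen. ILC2-like cells were set against the T-, B- and NK- or ILC1-like classes in a comparison added after the data were seen. By edgeR 770 of 3181 genes were called, 498 higher and 272 lower. These genes, apart from those kept out of the clustering, could be among the variable genes that helped to define the class. Outside the markers that named it, Csf2, Ccl1, Hs3st1, Ccdc184, Runx1t1 and Ramp3 were among the 10 largest increases. Ccl1, a chemokine ligand of Ccr8, stood at 714.3 ± 143.1 CPM (SD, n = 2) in ILC2-like and 11.9 ± 12.3 in T-like cells, and Hs3st1, a heparan sulfate sulfotransferase, at 892.4 ± 76.2 and 3.23 ± 4.56. Ramp3, a partner of the calcitonin receptor-like receptor, was at 1065 ± 115.6 and 672.8 ± 29.5 CPM. Il21r and Ccr7 were among the decreases, with 0 UMIs in ILC2-like cells. Kitl, the ligand of Kit, was at 329.6 ± 68 CPM in endothelial-like and 11.6 ± 3.23 in fibroblast-like cells.

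Tslp (ENSMUSG00000024379, chromosome 18, 32815383 to 32819797) was highest in macrophage-like cells, at 84.3 and 74.8 CPM against 19.6 and 26.6 in fibroblast-like cells (log2 fold change 1.95, SE 0.37, adjusted p = 3.31e-05, edgeR), with a UMI in 22 of 124 and 19 of 134 cells. Free RNA argues poorly for this, since the lymphoid classes had 0 UMIs, with an exact Poisson upper bound of at most 4.81 CPM, below the macrophage-like lower bounds of 56.9 and 47.4. Doublets with fibroblast-like cells would not exceed the fibroblast-like level, yet the ratio was at least 2.81 in both libraries, with intervals that do not overlap. The gene lies inside 4930455D15Rik (chromosome 18, 32663642 to 32837287), annotated on the other strand, which had 0 UMIs in macrophage-like cells; the exact Poisson upper bound of 12 CPM is too high to exclude UMIs of that gene, and whether counting used strand is not given in the sources used here. No biological explanation was tested.

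The pericyte-like cluster carried endothelial transcripts. Over the 50 genes with the highest fold of endothelial-like cells over any class other than the pericyte-like one, 4 of them the hemoglobin genes Hbb-bs, Hba-a2, Hbb-bt and Hba-a1, its CPM was a median of 0.737 and 0.769 of the endothelial-like level. Car3, which led the adipocyte-like cluster found at resolution 2.0, is also among the 50 genes. Free RNA would reach all classes alike, but the median ratio to the other non-endothelial classes was at least 47.7. The genes were chosen for low levels in those classes relative to endothelial-like cells, so the size of this ratio in part reflects the choice. Barcodes that hold a pericyte and an endothelial cell may account for the endothelial transcripts. The genes sat near 1 common ratio, with an interquartile range of at most 0.579 on the log2 scale. The median barcode had 2.08 and 1.52 times the UMIs of the endothelial-like class. The levels of 0.737 and 0.769 lie above what those UMI ratios alone would give a barcode with 1 endothelial cell, so the makeup of these barcodes stays open, and no biological explanation was tested.

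Fibroblast-like cluster 5 was weighed against dissociation stress and admixed RNA. Of the 19 stress genes 0 were higher and 6 lower over all genes tested, and 4 higher and 7 lower adjusted over the list alone. The list was not kept out of the clustering, so dissociation stress stays open. The test planned for doublets with or RNA from mesothelial-like or macrophage-like cells, the median ratio of their markers to the other clusters, was at most 1.0 for both but decides nothing, because 11 of 12 markers had at most 3 UMIs in cluster 5. From all marker UMIs together, the admixed share was at most 4.09% mesothelial-like and 0.452% macrophage-like, and at least 95.5% and 96.4% of the 110 higher genes exceeded what such shares allow. What sets cluster 5 apart stays open, and no biological explanation was tested.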
